A study of Populus trichocarpa with 32 samples.

How the data were processed

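The data are 1-colour NimbleGen oligonucleotide arrays of black cottonwood (Populus trichocarpa), 32 arrays of 16 tissues with 2 arrays per tissue. Total RNA was extracted with a spin-column kit and labelled in the array maker's pipeline, per the labels' protocols. The deposited scanner files give the intensity of each of 388340 spots as scanned, as whole numbers up to 65535, with no background subtraction or normalization, per the file headers and the values; their mismatch column is 0 throughout and was not used. The files list 65965 targets, and 62921 of them have 6 spots, namely 3 probes printed in each of 2 blocks of the array. A further 84 control spots carry 7 control sequences with 12 spots each. The authors' series table holds a log2 value per target and array, made with RMA per the submitters' processing notes; neither version nor software is given in the sources used here. The log2 scale of that table was inferred from its range, 3.45 to 15.96, and its values served only as an alternative to the scanner files.

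Each array's intensities were corrected with limma's normexp method (offset 50), quantile-normalized between arrays, taken to log2, and summarised per target by median polish with 10 iterations, which gave the same values as R's own function on simulated spots. A target is called a feature below. Where a target has several probes, the polish gives 1 value for all of them. One limma model with a mean per tissue was fitted to all 32 arrays (lmFit and eBayes; 16 residual degrees of freedom and 5.33 prior degrees of freedom), so that each comparison of 2 against 2 arrays uses the spread of all tissues. A feature was called at a Benjamini-Hochberg adjusted p under 0.05 within the comparison together with a difference of at least 2-fold. A tissue-preferential feature had an adjusted p under 0.05 against the mean of the 15 other tissues and a mean at least 1 log2 unit above every other tissue mean. R 4.3.3, limma 3.58.1, data.table (1.17.8), matrixStats 1.5.0 and statmod 1.5.0 were used. In simulated data with 200 changed features among 65965, the model recovered 52% to 65% of changes of 1.5 log2 units and 91% to 98% of changes of 3 log2 units over the 9 comparisons of paired tissues, and features without a change made up 1.97% to 6.17% of the calls. The simulated noise was independent between features and had 1 SD per feature in all tissues. In the measured arrays the median SD within a tissue ran from 0.10 log2 units in mature leaf to 0.46 in apex leaves. The simulated shares therefore need not hold for the measured comparisons.

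The tissues and replicate numbers follow the array titles. The title and source of the first apex-leaf array name leaves at the apex, while its tissue type gives plastochron 2, the label of the young-leaf arrays; the second apex-leaf array is labelled plastochron 1. A plastochron is the interval between successive leaves at the shoot tip. Mature leaves are labelled plastochron 5. The first array was kept with the apex leaves, and counting it as young leaf was an alternative. The series states 2 biological replicates per tissue except for phloem and cortex and for tissue-culture roots. The arrays of these tissues may differ by technical spread alone, and that spread enters the pooled variance behind the p-values of every comparison. The number of arrays, 2 per tissue, limits the precision.

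No table used here names the features: 0 of the 65965 target identifiers matched the gene table given for assembly P.trichocarpa_v4.1. The gene lists and cell type markers fixed before the data were examined could therefore not be tested, and genes are not named. By the rule fixed beforehand, at most 2 identifiers that rose and 2 that fell are given per comparison, those with the largest change among called features whose groups did not overlap. The planned filter on dim features needed random control probes, which were not recognised on this array, so that every feature was tested, as planned for that case. The control level is the 95th percentile of the normalized control spots of an array. In all named features of the 9 comparisons of paired tissues the dimmer tissue lay at or under it on both arrays, so that folds are given as bounds, the brighter tissue's mean against the control level of the dimmer tissue's arrays. Both measured means are given beside them. Without the brightest control sequence, an alternative added after the data were examined, the bounds were 0.905 to 1.38 times as large.

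Alternatives were no background correction, an offset of 0, median scaling, the mean of spots, the authors' table, no fold minimum, the compared tissues alone, a mean-variance trend with robust estimation, the replicate number as a block, leaving out each array, averaging the arrays not stated to be biological replicates, and regrouping the first apex-leaf array. Others were added after the data were examined. They were the image range as a block, a filter at the control level and a covariate meant to follow RNA quality. Also added were leaving out the 2 tissues whose arrays correlated least, and crossed replicate numbers. The files give no scan date. The image number in the file headers falls into 4 ranges, called image ranges here. The covariate is the gradient along the target, the difference between the last and the first probe, centred on its mean over the arrays. Its value on an array is the median over 13606 targets. Their probes span at least 500 positions and their level is above the 60th percentile. No direct measure of RNA quality was set against it. The files do not state which end of the transcript the positions count from. No 2 arrays held identical values.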

Results

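The series profiled vegetative, reproductive and seed tissues of black cottonwood, a tree with separate male and female individuals. Each of 16 tissues was hybridised to 2 arrays. They comprise phloem with cortex, developing xylem with pith, roots from tissue culture and from field trees, axillary buds, the shoot apex, leaves at the apex, young leaves, mature leaves, dry seed, seedlings 43 hours after imbibition, male and female floral bud initials, male catkins pooled over 3 stages, female catkins after pollination, and mature female catkins before seed release. The median spot intensity per array lay between 179 and 970. Across features, which are not independent replicates, the 2 arrays of a tissue correlated at 0.982 in mature leaf, 0.979 in male bud initials, 0.962 in seed and in field roots, 0.847 in young leaf, 0.822 in xylem and pith, and 0.570 in apex leaves. For 16 of the 32 arrays, the most similar array belonged to another tissue.

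Levels of 27941 of 65965 features (42.4%) differed among the tissues in limma's moderated F test at an adjusted p under 0.05. Only 10650 of the 65965 lay above the control level on both arrays of any tissue. Many of the 27941 therefore never rose above that level on both arrays of a tissue. Between tissue means, axillary buds and the shoot apex were closest to each other (r = 0.974 across features), and so were male and female bud initials (r = 0.958) and male and post-pollination female catkins (r = 0.951). Seed was closest to the seedling (r = 0.891), mature leaf to phloem and cortex (r = 0.900), and both root tissues to xylem and pith (r = 0.948 for culture roots, slightly more for field roots). The second xylem-and-pith array correlated with the 4 root arrays at 0.893 to 0.936, and the first at 0.856 to 0.895. With the second field-root array, however, the first correlated slightly more (0.895 against 0.893). The means of the 2 root tissues correlated at 0.936 with each other. Tissue means without the second xylem-and-pith array were not compared, so that its part in this closeness was not tested. Mature catkin lay farthest from the shoot apex (r = 0.577).

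With the main settings, seed had the most tissue-preferential features, 649 of 2166. Tissue-culture roots followed with 375, mature leaf with 302, the seedling with 298, field roots with 156, female bud initials with 108, the shoot apex with 94 and male catkin with 87. Phloem and cortex had 39, mature catkin 31, male bud initials 10, female catkin 4 and axillary buds 2. In seed, TREE0002S00038536 reached 14.24 ± 0.21 (log2, SD, n = 2, limma adjusted p against the mean of all other tissues = 1.15e-14). The seedling, the next tissue by normalized level, stood at 8.33, a difference of at least 25.6-fold. TREE0002S00001149 reached 13.21 ± 0.37 in male catkin (limma adjusted p against the mean of all other tissues = 2.02e-14). Culture roots stood at 7.55, a difference of at least 3.58 log2 units. Over female catkin, at 7.09 but with a higher control level, the bound was only 2.13 log2 units. In mature leaf, TREE0002S00010594 stood at 11.98 ± 0.27 (limma adjusted p against the mean of all other tissues = 2.33e-14). It was at 7.66 in female catkin, whose high control level leaves a bound of only 1.86-fold. TREE0002S00030616 of culture roots (13.42 ± 0.02, limma adjusted p against the mean of all other tissues = 5.52e-07) was at least 14.4-fold above field roots. Each of these comparison tissues lay at or under the control level on both arrays, so that their order among the dim tissues is not measured. Each bound holds against the named tissue alone, and these adjusted p-values do not test it. The 3 tissues with the lowest correlation between their arrays, apex leaves, xylem and pith and young leaf, had 6, 4 and 1. The order of the tissues depended on the settings. With the authors' deposited table the total was 4925, and mature catkin, with 696, came next after seed, with 1361, and before culture roots, with 636, while female catkin had 73. The scanner values of the second seed array matched another array's column of that table better than its own, which bears on the seed count there. An offset of 0 gave mature catkin 103, a filter at the control level left male catkin 22, mature catkin 5 and xylem and pith 0, and with the gradient as a covariate mature leaf, with 902, exceeded seed, with 560. With the first apex-leaf array counted as young leaf, apex leaves, then a single array, had 406, which placed them between seed, with 631, and culture roots, with 373.

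**Figure D1:**
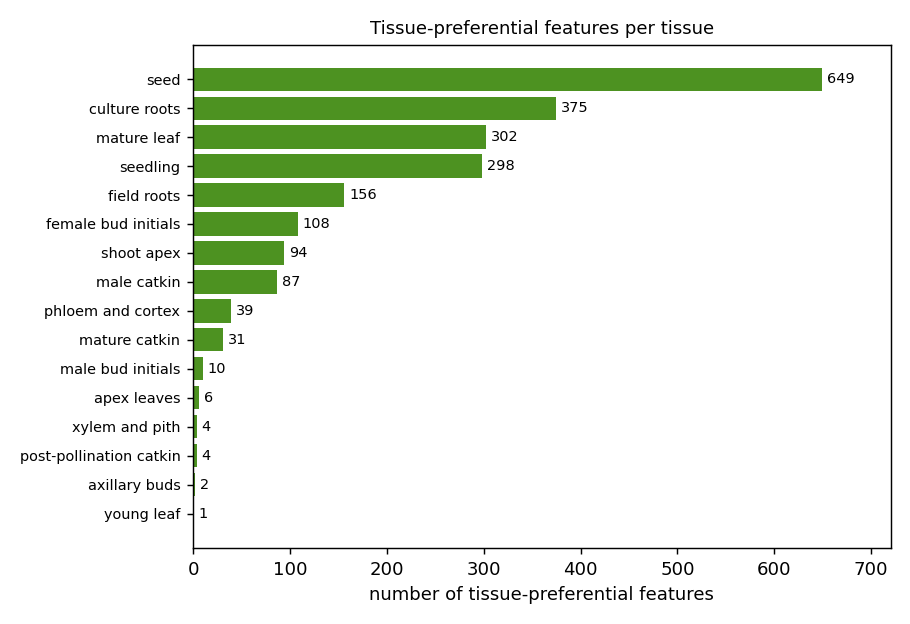
Number of tissue-preferential features (horizontal axis) in each of the 16 tissues, 2 arrays each; bars are counts without error. Seed leads with 649 features, and young leaf has 1.

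With the main settings, dry seed and germinating seedling differed in more features than the other pairs compared, 2113, of which 970 were higher in the seedling and 1143 lower. TREE0002S00027990 was at 15.09 ± 0.07 in the seedling and 8.63 ± 0.12 in seed (log2, SD, n = 2), at least 39.2-fold higher in the seedling (SE of the log2 difference 0.71, limma adjusted p = 2.70e-06). TREE0002S00002675 went the other way, 14.39 ± 0.19 in seed and 7.76 ± 0.11 in the seedling, at least 28.4-fold lower in the seedling (SE 0.29, limma adjusted p = 2.46e-12), and TREE0002S00030447 was at 13.89 ± 0.25 and 7.39 ± 0.14 in the same order. The count was 1109 without the second seedling array and 1136 without the second seed array. With the image range as a block it was 920, fewer than for roots (1204) and for mature against young leaf. The balance of directions turned without the first seedling array (1106 higher, 746 lower), with the authors' table (1152 and 1007, where the column of the second seed array correlated with its scanner values at only 0.839), with the 4 arrays alone (1700 and 1648), after a filter at the control level (787 and 764), without apex leaves and xylem and pith in the fit (1678 and 1580) and with the gradient as a covariate (2870 and 1525, 4395 in all). With that covariate mature against young leaf had more, 12095, and with the first apex-leaf array counted as young leaf both leaf comparisons did, 5145 and 2981 against 2446. No image range held arrays of both tissues.

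In the leaf series, mature leaf exceeded young leaf in 1132 of 1430 called features and fell below it in 298. TREE0002S00051843 rose from 8.95 ± 0.11 in young leaf to 14.67 ± 0.01 in mature leaf, at least 15.5-fold (SE 0.26, limma adjusted p = 1.47e-11), and TREE0002S00041873 from 8.35 ± 1.00 to 14.29 ± 0.11. TREE0002S00010179 stood at 13.79 ± 1.12 in young leaf and 9.33 ± 0.00 in mature leaf, at least 14.3-fold lower in mature leaf (SE 0.45, limma adjusted p = 1.50e-06). Differences from arrays that share none correlated at 0.50 and 0.40 across features. The gradient along the targets was 0.33 and 0.32 on the mature-leaf arrays and -0.16 and 0.03 on the young-leaf arrays. Leaving out 1 array gave 670 and 496 calls (first and second mature-leaf array) or 821 (first young-leaf array). With median scaling 1150 features were higher and 74 lower, with the gradient as a covariate 5166 and 6929, and the count was 736 from the 4 arrays alone and 2981 (1526 higher, 1455 lower) with the first apex-leaf array counted as young leaf. No image range held arrays of both tissues.

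Young leaf against apex leaves gave 799 called features, 511 higher in young leaf and 288 lower. TREE0002S00042553 was at 14.06 ± 0.35 in young leaf and 9.13 ± 0.47 in apex leaves, at least 16.5-fold higher (SE 0.29, limma adjusted p = 2.96e-09). TREE0002S00046739 was at 7.79 ± 0.26 and 13.99 ± 0.04, at least 9.68-fold lower in young leaf (SE 0.30, limma adjusted p = 7.93e-11). The differences between same-numbered arrays correlated negatively across features (r = -0.47), and between crossed ones weakly (r = 0.11), while the 2 apex-leaf arrays had gradients of 0.25 and -0.31. The 4 arrays alone gave 0 calls with limma, so that both named features lost their call there. At an unadjusted p under 0.05 they gave 1114 features, a smaller share of the 65965 than the 0.05 that pass without any difference. TREE0002S00042553 also lost its call with the first apex-leaf array counted as young leaf. Without 1 array the count was 143 (first young-leaf array), 1493 (second young-leaf array), 3846 (first apex-leaf array; 1819 higher, 2027 lower) or 4555 (second apex-leaf array), it was 5145 (2623 higher, 2522 lower) with the first apex-leaf array counted as young leaf, 2107 (1117 and 990) with the gradient as a covariate, 323 after a filter at the control level and 180 with the image range as a block. No image range held arrays of both tissues.

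Stem tissues were compared between the wood side and the bark side. Xylem and pith differed from phloem and cortex in 741 features, 187 higher and 554 lower. TREE0002S00046739 was at 14.13 ± 0.56 in xylem and pith and 7.67 ± 0.04 in phloem and cortex, at least 15.6-fold higher (SE 0.30, limma adjusted p = 3.32e-11), and TREE0002S00060374 at 13.75 ± 0.46 and 7.89 ± 0.44. TREE0002S00042553 was at 8.97 ± 0.43 in xylem and pith and 14.47 ± 0.55 in phloem and cortex, at least 22.1-fold lower (SE 0.29, limma adjusted p = 3.47e-10). Differences from arrays that share none correlated at 0.25 and 0.09 across features. The count was 188 without the second phloem-and-cortex array, 254 with the arrays of phloem and cortex and those of culture roots each averaged to 1 sample, 27 from the 4 arrays alone and 1951 with the gradient as a covariate. Without the first xylem-and-pith array it was 1583 (908 higher, 675 lower), and without the second, which correlated most with a culture-root array (r = 0.936), 747 (365 higher, 382 lower). No image range held arrays of both tissues, and with the range as a block 477 features were called.

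The stem and the leaf comparison shared features although they share no array. Of the 554 features higher in phloem and cortex and the 511 higher in young leaf, 286 were the same, where independent lists would share 4.29. Lower in both were 28 of 187 and 288 features, against 0.816 for independent lists (Fisher's exact test, two-sided p = 1.88e-34), and 0 features were called in opposite senses, where independent lists would share 2.42 and 1.45. TREE0002S00042553 lay between 13.79 and 14.87 on the 12 arrays of phloem and cortex, young leaf, mature leaf, male catkin, post-pollination catkin and mature catkin. On the 20 arrays of the 10 other tissues it lay between 8.42 and 9.46. TREE0002S00046739 divided the arrays in the same way, with 7.53 to 9.15 on those 12 arrays and 13.03 to 14.99 on the 20. In both comparisons 1 tissue lies on each side of this division, so that the differences between the tissues are confounded with whatever divides the arrays.

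**Figure D2:**
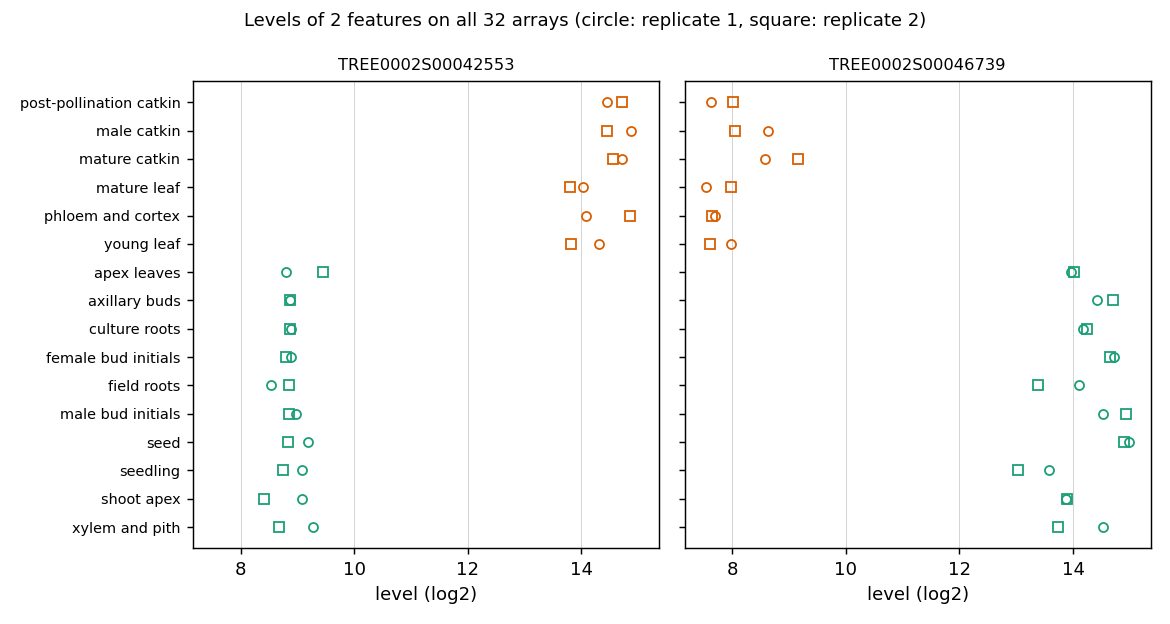
Normalized level (log2, horizontal axis) of 2 features on each of the 32 arrays, by tissue; circles are first and squares second replicates. The 12 arrays of 6 tissues (orange) reach 13.79 to 14.87 for TREE0002S00042553 and 7.53 to 9.15 for TREE0002S00046739, and no array of the 10 other tissues (green) lies in either range.

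Roots grown in tissue culture differed from roots of field trees in 819 features, 530 higher in culture and 289 lower. TREE0002S00000916 was at 14.72 ± 0.40 in culture and 8.83 ± 0.14 in the field (SD, n = 2), at least 35.5-fold higher (SE 0.99, limma adjusted p = 0.0021). TREE0002S00031924 was at 8.92 ± 0.10 and 14.48 ± 0.35, at least 28.8-fold lower in culture (SE 1.08, limma adjusted p = 0.0073). Differences from arrays that share none correlated at 0.33 and 0.73 across features. Image ranges 4 and 7 each held 1 array per tissue, and with the range as a block 1204 features were called. TREE0002S00031924 lost its call without any 1 of the 4 arrays (limma adjusted p = 0.0618 to 0.115), with median scaling (0.0898), with the authors' values (0.0848) and with the culture arrays and those of phloem and cortex each averaged to 1 sample (0.124), where TREE0002S00000916 lost it too (0.0541). Leaving out 1 array gave 284 or 304 calls (first or second culture array) and 323 or 254 (first or second field array). Averaging the culture arrays, and those of phloem and cortex, to 1 sample each gave 204, the authors' values 463, the 4 arrays alone 1978 and the gradient as a covariate 1819.

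Axillary buds and the shoot apex could hardly be told apart, with 6 called features, 5 higher in axillary buds and 1 lower. At an unadjusted p under 0.05 lay 1327 features, a smaller share of the 65965 than the 0.05 that pass without any difference. The other unadjusted counts in this paragraph are under that share too, so that none of them points to further differences. TREE0002S00038276 was at 10.42 ± 0.16 in axillary buds and 8.35 ± 0.38 in the shoot apex, at least 1.85-fold higher (SE 0.27, limma adjusted p = 0.0041). TREE0002S00019579 was at 8.11 ± 0.30 and 10.80 ± 0.20, at least 2.57-fold lower (SE 0.30, limma adjusted p = 7.15e-04). TREE0002S00038276 lost its call without either axillary-bud array (limma adjusted p = 0.0654 and 0.142) or the second shoot-apex array (0.338), with median scaling (0.0596), the authors' values (0.0523), the 4 arrays alone (0.205) or the first apex-leaf array counted as young leaf (0.0512), and TREE0002S00019579 without the second shoot-apex array (0.0733), with the authors' values (limma adjusted p = 0.244) or the 4 arrays alone (0.111). The 4 arrays alone and the authors' table gave 0 calls with limma, with 1579 and 955 features at an unadjusted p under 0.05. Without 1 array the count was 1 (first axillary-bud array), 2 (second) or 0 (second shoot-apex array; 969 at an unadjusted p under 0.05). Without the first shoot-apex array it was 7, of which 1 was higher and 6 lower and 2 were shared with the 6 above, so that the direction of the few differences stays open. Across all features, differences from same-numbered arrays correlated at -0.38 and those from crossed ones at 0.31. The count was 66 with the gradient as a covariate and 80 without apex leaves and xylem and pith in the fit.

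Male and female reproductive organs were compared in bud initials and in catkins. The sexes are separate trees, so that sex cannot be told apart from the individual tree in either organ. In bud initials, 42 features differed between the sexes, 10 higher in male and 32 lower. TREE0002S00063683 was at 13.25 ± 0.29 in male and 7.83 ± 0.26 in female bud initials, at least 10.5-fold higher in male (SE 0.37, limma adjusted p = 9.00e-08), and was also the leading feature preferential to male bud initials. TREE0002S00026006 was at 8.39 ± 0.32 in male and 12.61 ± 0.08 in female, at least 5.66-fold lower in male (SE 0.34, limma adjusted p = 1.18e-06). Image range 5 held 2 male arrays and 1 female array, and with the range as a block 28 features were called. Leaving out 1 array gave 10 or 20 calls (first or second male array) and 91 or 10 (first or second female array), while the authors' table gave 6, 3 in each direction, and the 4 arrays alone 7, of which 4 were higher in male and 3 lower.

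In catkins, 161 features differed between male and post-pollination female, 137 higher in male and 24 lower. The male catkins were pooled over stages and the female ones taken after pollination, so that sex cannot be told apart from stage here. TREE0002S00032629 was at 13.02 ± 0.34 in male and 6.81 ± 0.14 in female catkin, at least 3.81-fold higher (SE 0.24, limma adjusted p = 1.01e-12), and TREE0002S00001149 at 13.21 ± 0.37 and 7.09 ± 0.06. TREE0002S00019181 was at 8.55 ± 0.06 in male and 11.85 ± 1.45 in female (SE 0.46, limma adjusted p = 5.18e-04), and lost its call with the 4 arrays alone (limma adjusted p = 0.130). Its female mean was 1.72-fold above the control level of the male arrays. With this SD, the lower female array falls under the control levels of the 4 arrays (10.99 to 11.14). The fold thus rests on the higher female array and is not a bound. Across all features, the male-female differences from same-numbered arrays correlated negatively (r = -0.28), and those from crossed ones positively (r = 0.30). Image range 6 held 1 male and 2 female arrays, and with the range as a block 185 features were called. The count was 71 without the second male array, 81 without the first female array, 63 from the 4 arrays alone and 354 with the gradient as a covariate, which spanned -0.35 to -0.19 on these 4 arrays.

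The difference between the sexes itself differed between catkins and bud initials in 79 features, 67 with a larger male excess in catkins and 12 with a larger one in bud initials. The stages pooled in male catkins enter this difference of differences too. Across all features, its values from the first and from the second arrays correlated negatively (r = -0.28). TREE0002S00032629 was above the control level in male catkin alone among the 4 organs, at 13.02, with 6.81 in female catkin, 7.92 in male and 7.80 in female bud initials (limma adjusted p of the difference of differences 1.77e-09). TREE0002S00063683 was above it in male bud initials alone, at 13.25, with 9.57 in male and 9.54 in female catkin (limma adjusted p = 9.58e-06). The normalized levels do not measure the size of either difference of differences, since 3 of the 4 organs lie at or under the control level on both arrays. Called as higher in male in both organs was 1 feature, where independent lists of 137 and 10 would share 0.0208 (Fisher's exact test, two-sided p = 0.0206), and 0 features were lower in male in both. Leaving out 1 array gave 39 (second male catkin array), 43 (first female catkin array), 44 (second female bud array), and 41 or 52 (first or second male bud array).

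Between post-pollination and mature female catkin, 133 features differed, 90 higher in mature catkin and 43 lower. TREE0002S00003312 was at 13.83 ± 0.13 in mature and 7.55 ± 0.30 in post-pollination catkin, at least 6.71-fold higher (SE 0.32, limma adjusted p = 8.03e-11), and TREE0002S00029017 at 13.77 ± 0.57 and 8.02 ± 0.26. TREE0002S00027371 was at 7.18 ± 0.16 and 11.80 ± 0.56, at least 1.76-fold lower in mature catkin (SE 0.51, limma adjusted p = 3.28e-05). No image range held arrays of both tissues, and with the range as a block 32 features were called. Leaving out 1 array gave 57 or 72 calls (first or second mature array) and 51 or 220 (first or second post-pollination array), while the authors' table gave 262. The balance of directions turned with the gradient as a covariate (231 higher, 241 lower, 472 in all), with the 4 arrays alone (111 and 129) and without apex leaves and xylem and pith in the fit (192 and 221).

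**Figure D3:**
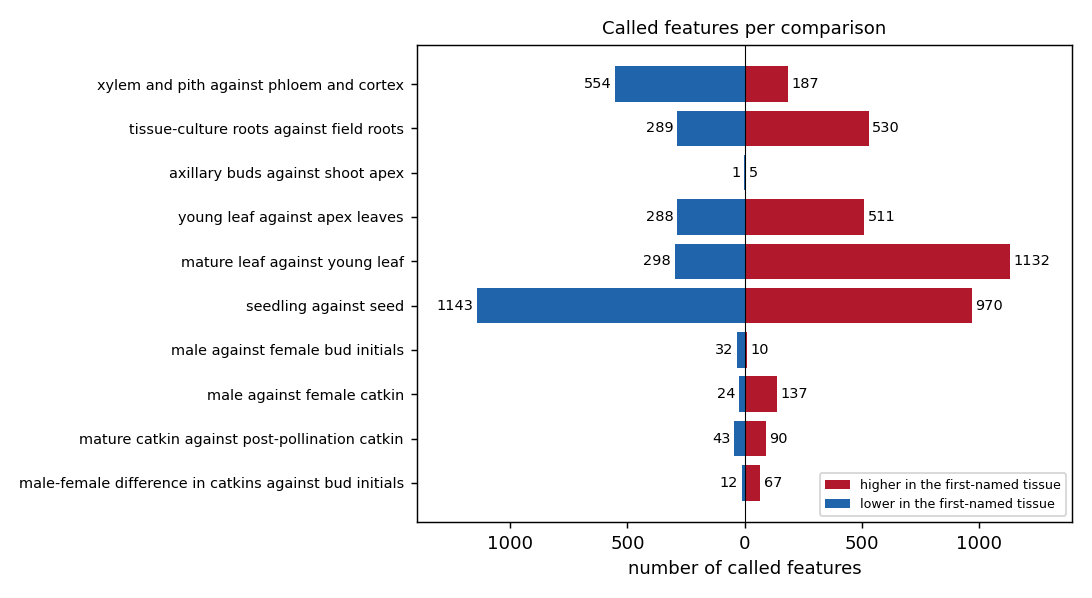
Number of called features in each of the 10 comparisons (horizontal axis), higher in the first-named tissue to the right and lower to the left; bars are counts without error, from 2 arrays per tissue. With the main settings, seedling against seed has the most, 970 and 1143, and axillary buds against the shoot apex the fewest, 5 and 1.

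**Figure D4:**
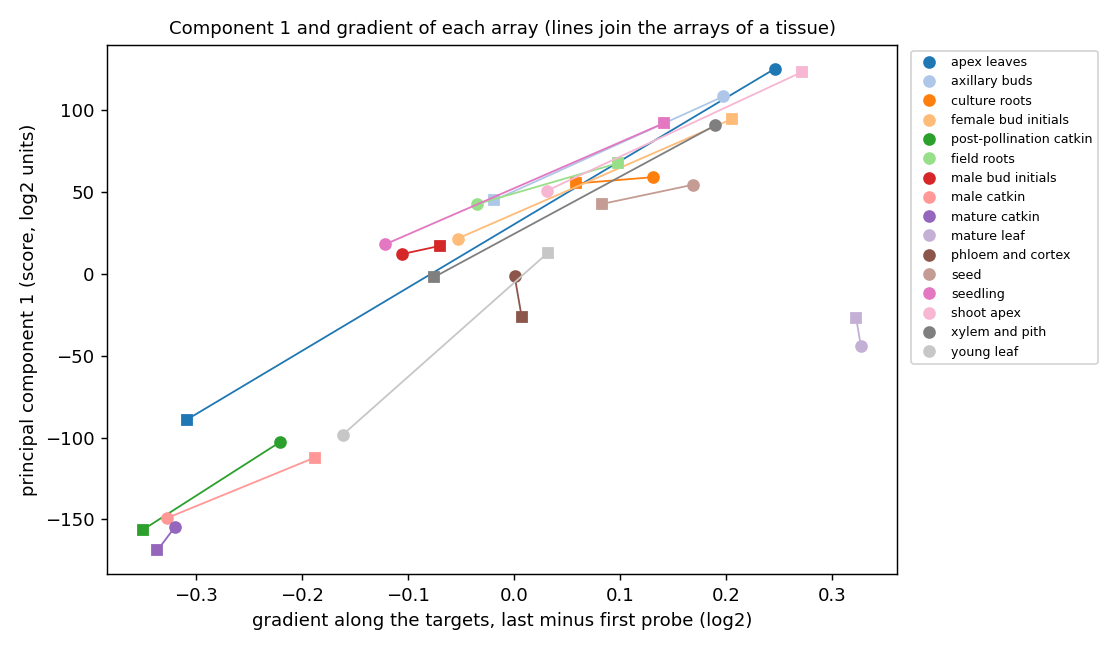
Score of each of the 32 arrays on principal component 1, which carries 39.0% of the variance (vertical axis), against the gradient along the targets (horizontal axis). The gradient is in log2 units relative to the average array. Lines join the arrays of a tissue, circles are first and squares second replicates. The 2 apex-leaf arrays lie farthest apart, at gradients of 0.25 and -0.31, and the 6 catkin arrays lie lowest on component 1.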

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

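All tests of the 3 patterns below were chosen after the patterns had been seen; for 4 of them, namely the slopes on the gradient in apex leaves and in xylem and pith and the 2 on root features, the prediction was written before the value was computed, and for the others (image range, genotype, sample preparation, plastochron, the gradient over tissues and between the 12 and 20 arrays, and culture-root features) after.

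The test of a difference between organs singled out 79 features whose difference between male and female was not the same in catkins as in bud initials. In normalized values, the differences of differences were 6.09 log2 units for TREE0002S00032629 and 5.83 for TREE0002S00001149, with a larger male excess in catkins, and -5.39 for TREE0002S00063683 and -4.46 for TREE0002S00006513, with a larger one in bud initials. In each of the 4, 3 of the 4 organs lay at or under the control level on both arrays, so that these values measure neither a size nor a rank. Outside the main measurement, the scanner values of the second seed array correlated with its column in the authors' deposited table at only 0.839, against 0.953 to 0.980 for the 31 other arrays. Each of those 31 matched its own column best, while the second seed array matched another array's column better. Its scanner values correlated with those of the first seed array at 0.962, while the deposited columns of the 2 seed arrays correlated at 0.824. The control spots, used here only for the control level, held 1 sequence that was brighter than the 6 others by 1.38 log2 units in mature leaf.

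The first pattern is the division of the tissues into 6 and 10. Among features whose 32 values leave 1 gap of at least 1.5 log2 units, 45 were higher and 2 lower on the 12 arrays of phloem and cortex, young leaf, mature leaf and the 3 kinds of catkin than on the 20 others, and the authors' deposited table gave 87 and 6. Image range is argued against, since 3 of the 4 ranges hold arrays of both sides. So is RNA quality, more weakly, since all 20 arrays lie inside the gradient range of the 12 (-0.35 to 0.33). The upper end of that range rests on mature leaf alone (0.32 and 0.33), and no other array of the 12 exceeded 0.03. A difference in sample preparation is a candidate explanation, since the brightest control sequence, a control rather than a plant target, stood 0.63 to 1.56 log2 units above the 6 others on the 12 arrays and -0.30 to 0.38 on the 20, a gap of 0.25, although cross-hybridisation of a plant transcript to that control stays open. Genotype cannot be told apart, since 1 of the 12 arrays and 7 of the 20 are labelled with the reference genotype Nisqually-1 and most carry no such label; tissue identity, season and time of harvest were not tested.

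The second pattern is that arrays of 1 tissue differ along component 1, which carries 39.0% of the variance. Over the 16 tissues, the difference between the 2 arrays on component 1 followed their difference in gradient (Pearson r = 0.968, Spearman rho = 0.938, permutation p = 1.0e-05 for both, the smallest that 100000 permutations can give), also without apex leaves and xylem and pith, whose gradient differences lay farthest from the median (r = 0.925), and with component 1 taken from the 52359 targets that do not enter the gradient (r = 0.969). In apex leaves, slopes on the gradient learned from the 15 other tissues predicted the difference between the arrays (r = 0.819 across features, p = 0.0020 from 1000 sign flips, whose 95th percentile was 0.749), which is consistent with a difference in RNA integrity or label length, while mature leaf, at gradients of 0.33 and 0.32 but component scores of -44.2 and -26.9, departs from that relation between tissues. Image range cannot be told apart, since the 8 tissues with arrays in 2 ranges differed by a median of 50.2 and the 8 within 1 range by 35.3, a difference of 14.9 (permutation p = 0.718). The plastochron in the labels stays open too, since the first apex-leaf array was closer than the second to the second young-leaf array (r = 0.884 and 0.712) and farther from the first (r = 0.660 and 0.800, a difference of -0.139).

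The third pattern is the second xylem-and-pith array, which correlated at 0.822 with its own replicate and at 0.936 with the second culture-root array. Its mean correlation with root arrays of another image range, 0.907, exceeded by 0.0767 its highest correlation with arrays of tissues other than roots in its own range (0.831), which argues against the range. Slopes on the gradient predicted its difference from the first array in part (r = 0.582 across features, p = 0.0200 from 1000 sign flips). They predicted only 2.96% of the median difference of 1.62 log2 units in 220 features preferential to roots, chosen without stem tissues. These features were chosen for lower levels in the tissues that gave most of the slopes, which limits the slopes. This share therefore cannot decide whether RNA quality is the whole cause. On a scale from the other tissues (0) to roots (1), these features stood at 0.0759 on the first array and 0.796 on the second, a difference of 0.720. With a gap of at least 1.5 log2 units, 55 features set it and both culture-root arrays above the 29 others, 0 set it and both field-root arrays above them (a difference of 55), and 0 were shared by both xylem-and-pith arrays alone, so that root RNA from culture in this array, or a wrong label, may account for the pattern, and a real difference between the 2 xylem samples was not tested.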

How the results depend on the processing

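The settings marked as added were chosen after the data were examined, namely the image range, the control-level filter, the gradient, the crossed numbers, and leaving out apex leaves and xylem and pith; the others were fixed before. Counts within 1.5 times the main one are not repeated. No named feature changed direction in any setting, but in many settings it could not have. Features of paired tissues were named only where the groups did not overlap, so that leaving out 1 array could not turn them. Settings that kept the tissue means could not turn them either. The direction is therefore informative mainly where the values, the grouping of the arrays or an unbalanced covariate changed. Over all settings, 637 values stayed called and 73 lost the call. Among the named features of the roots comparison, 3 of 4 lost it without any 1 of the 4 arrays. The causes of the changes below were not tested, except that fewer arrays or features enter some fits. The planned filters were not run, since random control probes were not recognised: no filter is the main setting, and the 99th percentile of such probes has no value. Dim signals limit the folds, because the dimmer tissue of the named features lay at or under the control level.

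Without background correction, axillary buds against the shoot apex gave 19 called features and young leaf against apex leaves 458. An offset of 0 gave 2 for axillary buds, 19 for the sexes in bud initials and 47 for the difference between organs. Median scaling gave 26 in bud initials and 67 for mature against post-pollination catkin, and turned the split of mature against young leaf from 79.2% to 94.0% higher. The mean of spots gave 1458 for xylem and pith, 14 for axillary buds and 1418 for young leaf. The authors' table gave 463 for roots, 0 for axillary buds (limma; 955 at an unadjusted p under 0.05), 6 in bud initials (3 higher and 3 lower, against 23.8% higher in the main setting), 262 for mature catkin, 41 for the difference between organs and 4925 tissue-preferential features. A gap of 2 log2 units left 441 tissue-preferential features. Trend and robust estimation gave 2 for axillary buds. The compared tissues alone gave 27 for xylem and pith, 1978 for roots, 0 for axillary buds (limma; 1579 unadjusted), 0 for young leaf (limma; 1114 unadjusted), 736 for mature leaf, 3348 for the seedling, 7 in bud initials, 63 in catkins, 240 for mature catkin and 35 for the difference between organs. Averaging the arrays not stated to be biological replicates, in both tissues at once, gave 254 for xylem and pith and 204 for roots. The first apex-leaf array counted as young leaf gave 10 for axillary buds, 5145 for young leaf and 2981 for mature leaf.

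Among the added settings, the image range as a block gave 477 for xylem and pith, 180 for young leaf, 920 for the seedling and 32 for mature catkin. The control-level filter, which kept 10650 features, gave 323 for young leaf, 89 in catkins and 8919 features that differ among tissues. The gradient as a covariate gave 1951 for xylem and pith, 1819 for roots, 66 for axillary buds, 2107 for young leaf, 12095 for mature leaf, 4395 for the seedling, 99 in bud initials, 354 in catkins, 472 for mature catkin and 179 for the difference between organs. Leaving out apex leaves and xylem and pith gave 1689 for roots, 80 for axillary buds, 2725 for mature leaf, 3258 for the seedling, 101 in bud initials, 320 in catkins, 413 for mature catkin and 146 for the difference between organs.

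Leaving out each array in turn, where a lone array is assumed to vary like the other tissues, gave 188 to 1583 calls for xylem and pith, 254 to 323 for roots, 0 to 7 for axillary buds, 143 to 4555 for young leaf, 496 to 1733 for mature leaf, 1109 to 1852 for the seedling, 10 to 91 in bud initials, 71 to 142 in catkins, 51 to 220 for mature catkin, and 39 to 88 for the difference between organs. For tissue-preferential features all first or all second arrays were left out together. This leaves the tissues without replicates, so that no adjusted p could enter. The counts, 3019 and 2252, rest on the gap above every other tissue alone. They follow a looser definition than the main count and cannot be compared with it directly.

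The replicate numbers did not pair the arrays: over 120 pairs of tissues, deviations of same-numbered arrays correlated at -0.66 to 0.67 with a median of -0.01, and 36 pairs exceeded 0.1. The replicate block gave 2 calls for axillary buds and left the other counts within 1.5 times. With crossed numbers, for the 5 comparisons with a correlation under -0.1, the counts were 774 for roots, 9 for axillary buds, 1491 for young leaf, 2094 for the seedling and 169 in catkins.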

Other observations

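The hypotheses in this part were written down before their tests were run. Each takes the features that stood at least 1 log2 unit above the other tissues in 1 tissue, chosen without the arrays they were then tested on, and asks how they moved in another comparison. There were 5 such tests; p is that of limma's fry, adjusted over the 5 tests (Benjamini-Hochberg), and percentiles are among 10000 random lists matched on mean level.

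The median of the seed features was slightly higher in mature than in post-pollination catkin, although most of them were not called. Of 916 seed features, 36 were called higher in mature than in post-pollination catkin, 0 lower and 880 not called (65 higher and 1 lower adjusted over the list alone), with 595 above 0. Their median difference was 0.17 log2 units (limma fry adjusted p = 0.0236, above 100% of the random lists), and 0.16 to 0.22 over the 4 pairs of arrays. Seed RNA in catkins harvested before seed release is a possible reading, although the interquartile range of the members, -0.12 to 0.52, spans 0. The test does not separate it from a shift of dim features between the catkin arrays.

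The median of the mature-leaf features was higher in the seedling than in seed, although most of them were not called. Of 798 mature-leaf features, 173 were called higher in the seedling than in seed, 20 lower and 605 not called (250 higher and 27 lower adjusted over the list alone). The median difference was 0.61 log2 units (limma fry adjusted p = 0.0194, above 100% of the random lists) and 0.31 to 1.05 over the 4 pairs of arrays. The values are in line with part of a leaf programme being under way 43 hours after imbibition.

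For the same 798 features, the test left the direction open in the 2 other pairs. Between young leaf and apex leaves, 7 were called higher, 1 lower and 790 not called, with a median of 0.14 (limma fry adjusted p = 0.552) and medians of -0.65 to 0.84 over the 4 pairs of arrays. Between xylem and pith and phloem and cortex, 0 were called higher, 26 lower and 772 not called, with a median of -0.27 (limma fry adjusted p = 0.268), although each pair of arrays gave a median below 0 (-0.37 to -0.14). Both medians lay outside the random lists, above 100% and above 0% of them.

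For the 182 features of male catkin, chosen without bud initials and female catkins, the test left the direction between male and female bud initials open, with a median of 0.17 log2 units (limma fry adjusted p = 0.481) and 150 above 0, although the median lay above 100% of the random lists. Over the pairs of arrays the median ran from -0.01 to 0.39, and 1 feature was called higher, 0 lower and 181 not called. A male programme in bud initials could be neither excluded nor shown.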
